A study of Mus musculus with 2 samples.

How the data were processed

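DNase-seq was done on neural tube tissue of mouse embryos (strain B6NCrl, pooled males and females) at 10.5 days. Per the labels the 2 libraries are biological replicates 1 and 2, with 1 technical replicate each and the same donor entry for both. They form 1 group, so no comparison between groups was possible. Sequencer models are named for replicate 1 only, so a difference in batch was not tested.

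Per library, the authors deposited 3 peak lists, hotspots (broader open regions), 2 lists of per-base false discovery rates (FDR) and footprints, all on the mm10 build. They come from 2 processing runs of each library. The aligner, the peak caller and their versions are not given in the sources used here. In the longest peak list, from the other run than the footprints, the deposited signal is a whole-number peak height that is not scaled to depth, and over 99% of peaks have a width of 150 bp. In the 2 remaining peak lists the signal deposited is a height scaled to depth. In the hotspots, the authors' values are −log10 of the smallest FDR of the hotspot, capped, and the deposited score is that value times a constant. The deposited p-values are FDR values per base, listed only where under 0.05. Every peak of the stricter list held a base with an FDR under 0.001. The footprint list carries a constant that was not used here. Heights and scores are the authors' own.

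No read counts were used here. The scaled heights are whole multiples of 1 step per library, and the inverse of that step gave scaling totals of 247.9 M tags for replicate 1 and 210.5 M for replicate 2, a ratio of 1.18. These totals are inferred from the values. They come from the other processing run than the longest list, whose heights they were used to scale. In the longest list the median height was 113 in replicate 1 and 92 in replicate 2, with a lowest value of 6 in both. A site without a peak may hold signal below the authors' threshold, so an absent peak is not a measured 0. Intervals cover counting error only.

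Before the data were examined, the comparisons, gene lists, words, main settings and most alternative settings were fixed. The longest peak list per library was used by a rule fixed then. Peaks of both libraries that overlapped by at least 1 bp were merged, and a merged interval with a peak of both was called shared. Agreement was measured by Spearman coefficients of height and Pearson coefficients of log2 height with a pseudocount of 1 (0.005 for scaled heights). Chance overlap came from 20 random placements.

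Genes were the 21644 protein-coding genes of GENCODE release M21, on the same build, on the autosomes and X. Each had 1 TSS, of the transcript with the best APPRIS level and then the longest. A promoter was open when a shared peak lay within 1 kb of the TSS. A peak was distal when its midpoint was over 1 kb from every protein-coding TSS, and was counted for each gene within 50 kb. The 21 gene lists were written from general knowledge: 7 neural lists and lists for patterning signals, notochord and floor plate, Hox genes, receptors of smell, housekeeping, non-neural developmental transcription factors and 8 other tissues. Lists overlap, so a gene such as Hand2 counts in each list that holds it.

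Promoter shares were tested with Fisher's exact test against all other genes, with exact Clopper-Pearson 95% intervals. Distal counts were tested against 10000 random lists of the same size. Both were adjusted over the 21 lists by the Benjamini-Hochberg method at 0.05. Neural and non-neural transcription factor genes, after genes of both sides were dropped, were compared by 100000 permutations, with 10000 bootstrap draws for the interval. Hox genes and introns were described without a test between clusters or loci.

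For 44 sequence words, searched on both strands, windows of 200 bp at shared distal peaks were paired with windows 1 kb downstream that overlapped no peak, and compared by exact McNemar tests with adjustment over the words. A word stands for a family of factors and does not show which protein binds. Matches in peaks were compared with footprints after 100 random placements of each match within its peak.

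The text names these genes by a rule fixed beforehand. They are, for each list, the 2 members with the most and up to 2 with the fewest shared distal peaks, and up to 2 without a shared promoter peak. Also named are the 20 genes with the most shared distal peaks, the 10 highest shared distal peaks by mean rank, Nes, Shh, Pax6, Lmbr1, Sox2, Olig2 and the Hox genes, and for each library the 5 highest peaks it alone had. Some genes that the rule names are not reported here.

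The alternatives fixed then were a 50% reciprocal overlap, the stricter list, equal numbers of peaks, shared peaks only, pseudocounts of 10 and 0.1, promoter windows of 500 bp and 2.5 kb, neighbourhoods of 20 and 100 kb, each library alone, the median in place of the mean, and random lists matched in 5 strata on promoter CpG content (500 bp either side of the TSS) or gene density. For words they were upstream windows, windows of 100 bp and windows shuffled with their dinucleotides kept. For footprints they were a reciprocal overlap and shared peaks only. Chosen after seeing the data were the longer list of scaled heights, hotspots, any TSS of a gene, a peak of each library in the promoter window without overlap, and all alternatives for the introns.

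The tests were tested on simulated data. In random lists of 25 genes an unadjusted p under 0.05 came in 6% of 200 lists for promoters and in 5.5% for distal peaks, and in 4% of 50 random splits for the transcription factor comparison. Planted differences were called in 20 of 20, 19 of 20 and 49 of 50 cases. Of the 44 words, 0 were called in shuffled windows, and a word planted in 5% of windows was recovered in 4.97%, with 1 other word called that shares its sequence.

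Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and sequences were matched with blastn 2.17.0. Genes on chromosome Y were left out, since much of its sequence is repeated, and the receptor genes were left out of the summary of CpG-rich peaks, since their list is far longer than the others.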

Results

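DNase-seq maps open chromatin as sites that the nuclease DNase I cuts. The 2 libraries here came from neural tubes of mouse embryos at 10.5 days, biological replicates 1 and 2 of the same strain. There was 1 group, so no groups were compared. The comparisons below are between gene lists, between sites and their surroundings, and between the 2 libraries. A shared peak is an interval with a peak of both libraries. Genes and peaks are not replicates of the tissue, so each p describes these 2 libraries.

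In replicate 1, 148508 peaks were listed and in replicate 2, 110912. Of the peaks of replicate 1, 48.4% overlapped a peak of replicate 2, and of the peaks of replicate 2, 66.1% overlapped a peak of replicate 1. With the peaks of replicate 2 placed at random, the overlap was 1.30% of the peaks of replicate 1. Merged over both libraries the peaks formed 183730 intervals, of which 69438 were shared, 76646 were in replicate 1 only and 37646 in replicate 2 only. Peak heights correlated at a Spearman coefficient of 0.909 over shared peaks and 0.286 over all intervals. The Pearson coefficient of log2 heights was 0.91 over shared peaks and -0.11 over all intervals, where an absent peak counted as a height of 0.

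Shared peaks were higher in replicate 1. Scaled to depth, their median height was 0.827 in replicate 1 and 0.527 in replicate 2, a median ratio of 1.56. The ratio was 1.69 at promoters and 1.5 at distal sites, and 92.4% of the shared peaks were higher in replicate 1. The highest peaks found in replicate 1 only lay nearest Vcl (height 1599), Smarca4 (1542), Mbd3 (1484), Zfpm1 (1484) and Cnnm2 (1399). Those in replicate 2 only lay nearest Kcnab2 (509), Ranbp1 (500), Zfpm1 (485), Atf4 (481) and Ints7 (476). All 10 lay within 10 to 170 bp of a peak of the other library, and the 2 peaks nearest Zfpm1 lay 30 bp apart.

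Promoters, taken as 1 kb either side of a transcription start site (TSS), held 29.8% of the shared peaks (exact 95% interval 29.5 to 30.2%) and 2.03% of the genome, a ratio of 14.7. Exons held 6.66% of the shared peaks against 3.50% of the genome. Introns held 32.9% against 41.1%, and intergenic sequence 30.7% against 53.4%. Replicate 1 alone gave 20.4% at promoters and replicate 2 alone 29.4%.

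The highest shared distal peak lay 35.5 kb from Pak3 on chromosome X, with heights of 7118 in replicate 1 and 9445 in replicate 2. The next lay 16.7 kb from Limd1 (5959 and 1986), 5.48 kb from Cd209a (4292 and 1620) and 1.56 kb from Kpna1 (3740 and 1390). They were followed by peaks nearest Rpp21 (2817 and 1557), Dtnbp1 (3639 and 1321) and Ddx18 (2558 and 995). A pair of peaks nearest Cr2 (1974 and 757, and 1744 and 1042) and a peak nearest Plekha1 (1762 and 837) completed the 10.

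Every gene in the lists of spinal neuron subtype transcription factors (29 genes) and of forebrain and midbrain transcription factors (20 genes) had a shared promoter peak. Across all 21644 protein-coding genes 59.5% had one. Pax3, which marks dorsal progenitors, had promoter heights of 497 and 253 in replicates 1 and 2, Foxa2 of the floor plate 251 and 161, and Lbx1 of dorsal interneurons 326 and 254. The immune genes Mpo and Elane and the hepatocyte genes Alb and Afp had no promoter peak in either library.

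By Fisher's exact test with Benjamini-Hochberg adjustment over 21 lists, 9 lists lay above the other genes and 6 below. Above were spinal neuron subtype factors (100%, adjusted p 3.54e-06), housekeeping genes (100%, 2.45e-05), forebrain and midbrain factors (100%, 0.000155), neurogenesis and pan-neuronal genes (95.8%, 0.000309) and neural progenitor genes (95.2%, 0.00122). Patterning signals (91.7%, 0.00162), somite and mesenchyme genes (90.9%, 0.00388), dorsoventral progenitor factors (88.5%, 0.00406) and neural crest genes (91.7%, 0.0486) were also above. The neural crest list passed the threshold in only 1 of its 9 alternative settings, the 2.5 kb promoter window. With a 500 bp window the neural progenitor (76.2%, adjusted p 0.110) and somite lists (77.3%, 0.0845) did not pass it, and with the stricter peak list the somite (81.8%, 0.107) and patterning lists (83.3%, 0.0514) did not. Either of these settings left 6 lists above.

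Below were olfactory and vomeronasal receptor genes (0.478%, 7 of 1463 genes), immune genes (6.67%, adjusted p 0.000155), Hox genes (30.8%, 0.00122), pluripotency and germ cell genes (20%, 0.00453), erythroid genes (25%, 0.0126) and liver and gut genes (25%, 0.0126). For Hox genes the direction depended on replicate 2. With replicate 1 alone 84.6% of their promoters were open, above the other genes (adjusted p 0.0254). Past no threshold were mature synapse and glia (70.6%, adjusted p 0.510), endothelial (46.7%, 0.503), heart and muscle (60.0%, 1.00), epidermis (53.3%, 0.642) and non-neural developmental factors (51.9%, 0.324). The 8 notochord and floor plate genes (87.5%, exact test, adjusted p 0.202) did not pass it either.

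Fewer lists differed from random lists matched on promoter CpG content. Above were 3 lists: neurogenesis genes (23 open against a random mean of 16.2, permutation, adjusted p 0.00315), somite and mesenchyme (20 against 15.2, 0.0349) and heart and muscle (9 against 5.36, 0.0472). Below were germ cell genes (3 against 9.18, 0.00140), Hox genes (12 against 30.7, 0.00105) and the receptor genes (7 against 106, 0.00105). The spinal list (29 open against 25.5) and the forebrain and midbrain list (20 against 17.4) could not pass this test. All their genes were open and matched random lists also reached 29 and 20. Housekeeping genes, all open, lost the call too. So did the neural progenitor, dorsoventral, patterning and neural crest lists, which were not fully open.

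Among listed genes without a shared promoter peak, Jag1, a Notch ligand, had peaks of 894 and 300 in the 2 libraries that did not overlap each other. Irx3 (512 and 297), Smo (803 and 300), which carries the Hedgehog signal, and Cyp26b1 (124 and 71) were alike. Dbx2 (77), Nhlh1 (172), Noto (93) and the muscle factors Myf5 (125) and Myog (102) had a promoter peak in replicate 1 only. Cdx1 had a promoter peak in replicate 2 only (137).

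**Figure D1:**
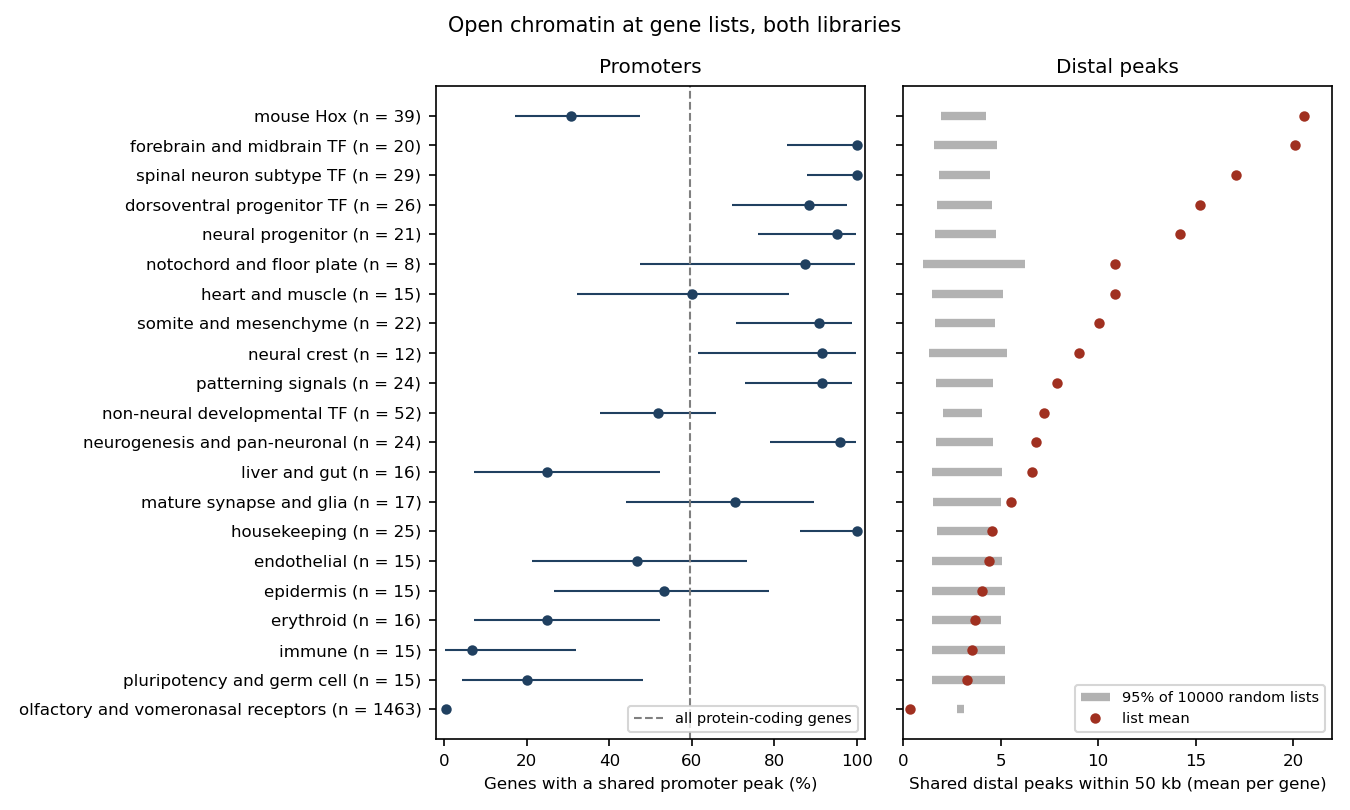
Left, share of each list's genes with a shared promoter peak, with exact 95% intervals. Right, mean number of shared distal peaks within 50 kb and the range of 95% of random lists.

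Distal peaks crowded around genes of neural development. Within 50 kb of their TSS, Dlx6 had 39 shared distal peaks, Zic1 41, Tfap2b 34, Sox2 33, Lbx1 33, Barhl2 32 and Pax3 31, against a mean of 2.94 (SD 3.66) over all genes. At the other end Map2, Rbfox3, Ednrb and Snai2 had 0. Some transcription factor genes of other organs had as many, with 36 near Hand2, a heart factor, 35 near Tbx5 and Pdx1, and 29 near Cdx2, while Alb and Afp had 2, the median of all genes. Pdx1 and Cdx2 are neighbours, with TSS at 147269959 and 147307270 on chromosome 5, so their windows overlap and count some peaks for both.

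Against 10000 random lists, 15 lists were above and 1 below. The mean was 20.1 for forebrain and midbrain factors (6.84 times the random mean), 17.1 for spinal neuron subtype factors (5.81), 15.2 for dorsoventral progenitor factors (5.18) and 14.2 for neural progenitor genes (4.82). Hox genes had 20.6 (6.98), though neighbours in a cluster count the same peaks, as do Dlx5 and Dlx6 in the forebrain and midbrain list. Random lists draw scattered genes, so for lists with such neighbours p can be too small. For each of the lists just named the permutation p was 1e-04, the smallest that 10000 lists can give. The same p held for heart and muscle (10.9, 3.71 times), somite and mesenchyme (10.05, 3.42), neural crest (9.00, 3.07), patterning signals (7.88, 2.68) and non-neural developmental factors (7.23, 2.46). Medians were 18.5 for forebrain and midbrain, 18 for spinal, 15 for dorsoventral and 11 for neural progenitor lists, but 5 for heart and muscle, 7.5 for somite and mesenchyme, 6 for neural crest, 7.5 for patterning signals and 4.5 for non-neural factors. A few genes with many peaks thus raised the means of heart and muscle and of neural crest, such as Hand2 and Tbx5 in the former and Tfap2b (34) in the latter.

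Notochord and floor plate genes had 10.9 (3.71 times, permutation, adjusted p 0.000323), neurogenesis genes 6.79 (2.31, 0.000323), liver and gut genes 6.63 (2.26, 0.00270), synapse and glia genes 5.53 (1.87, 0.0158) and housekeeping genes 4.56 (1.55, 0.0396). Their medians were 9, 5.5, 2, 5 and 4. The liver and gut median was that of all genes, and Pdx1 and Cdx2 held a large part of its peaks. Housekeeping genes lost the call in 4 of 8 alternative settings, and synapse and glia genes in the stricter peak list (1.53 times, adjusted p 0.133). Receptor genes had 0.364 (0.124 times, p 1e-04), with 18 peaks near Olfr750 and none near Olfr1. Not called were endothelial (4.40, adjusted p 0.132), epidermis (4.07, 0.228), erythroid (3.69, 0.427), immune (3.53, 0.560) and germ cell genes (3.27, 0.743). Against lists matched on promoter CpG content, erythroid genes were called (1.78 times, adjusted p 0.0394).

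Among the 20 genes with the most shared distal peaks were Cbx8 (50) and Cbx2 (38), which encode Polycomb proteins. Nr2f2 had 42, Gm21887, Zic1 and Zic4 had 41, and Hoxb13 had 40. The cell cycle inhibitors Cdkn2a and Cdkn2b, Dlx6, Foxf1 and Mthfsd had 39, and Dlx5 and Foxc2 had 38. Nkx2-3 and Tbx15 had 37, Hand2 had 36, and Gm5089 and Pdx1 had 35.

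The 55 neural transcription factor genes had a mean of 16.2 shared distal peaks (SD 8.33) and the 52 non-neural ones 7.23 (SD 8.53). The difference was 8.97 (bootstrap 95% interval 5.69 to 12.0), with a permutation p of 1e-05, the smallest that 100000 resamples can give. Among the non-neural genes Hand2 had 36 and Pdx1 35, while Myf5 and Runx2 had 0. The neural and non-neural genes were not matched with each other on promoter CpG content or gene density. Against random lists matched on CpG content, the spinal list stood at 4.85 times the random mean, dorsoventral at 4.31 and non-neural at 2.52. With matching on gene density these were 6.35, 5.74 and 2.53.

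In the Hox clusters, genes with shared promoter peaks included Hoxa2, Hoxb1, Hoxb2, Hoxc4 and Hoxd1, and also Hoxa5, Hoxa13, Hoxb13, Hoxc11, Hoxc13 and Hoxd13. Of paralog groups 1 to 4, 6 of 12 genes had one, of groups 5 to 8, 1 of 11, and of groups 9 to 13, 5 of 16. Replicate 1 had a peak at 33 of the 39 promoters and replicate 2 at 14. In the same order of groups, these were 12, 9 and 12 in replicate 1 and 7, 2 and 5 in replicate 2. At 19 genes, with heights from 229 (Hoxd4) to 1031 (Hoxc10), replicate 1 had a promoter peak and replicate 2 had none.

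The clusters held 30 (Hoxa), 56 (Hoxb), 23 (Hoxc) and 35 (Hoxd) shared peaks. Replicate 1 alone had 87, 111, 77 and 111 peaks there, and replicate 2 alone had 51, 87, 33 and 47. In replicate 2 the longest stretch without a peak was 72.6 kb in Hoxb, from 96267086 to 96339695 on chromosome 11, which covers the TSS of Hoxb3 to Hoxb9 and holds 37 peaks of replicate 1. Such stretches were 52.0 kb in Hoxd (55 peaks of replicate 1), 38.8 kb in Hoxc (26) and 33.7 kb in Hoxa (1). In replicate 1 the longest were 28.8 kb in Hoxb, 18.6 kb in Hoxa, 9.94 kb in Hoxc and 6.25 kb in Hoxd. Hoxa also had a sparse stretch in replicate 2, between 52176114 and 52202988 on chromosome 6. It held 1 peak of replicate 2, at 52192076, and a run of peaks of replicate 1 with heights up to 788.

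**Figure D2:**
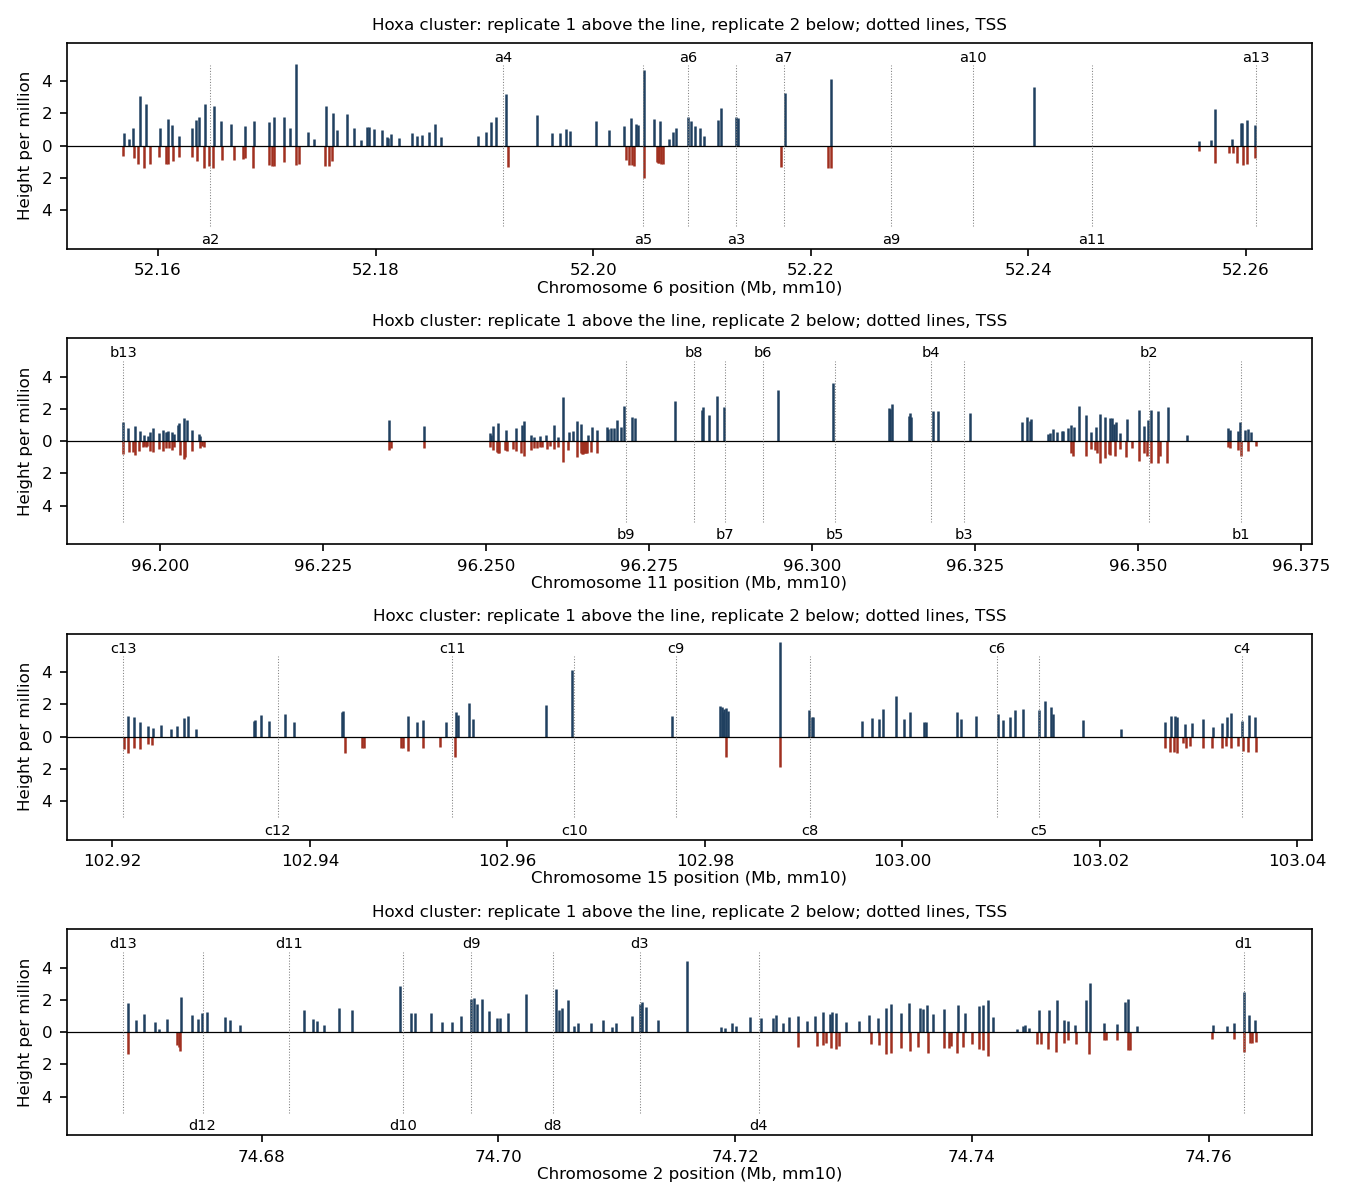
Peaks of both libraries along the 4 Hox clusters, with heights scaled to depth. In replicate 2, long stretches of Hoxb, Hoxc and Hoxd hold no peak, and peaks are sparse over part of Hoxa.

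At Shh, which encodes the floor plate signal, intron 2 held 3 shared peaks, the strongest at 28459916 to 28460085 on chromosome 5 (heights 317 and 219). Intron 5 of Lmbr1 held 1 (262 and 103). The introns of Pax6 held 25, of which 15 lay in intron 1, 4 in intron 3, 1 in intron 6 and 5 in intron 7. Intron 2 of Nes held none, and 1 peak of replicate 1 alone. Within 50 kb of the TSS there were 36 shared peaks at Sox2 and 23 at Olig2, promoter peaks included. With replicate 1 left out there were 55 and 39, and with replicate 2 left out 52 and 49. The introns of Pax6 then held 32 in either case.

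CTCF, the insulator protein, had its word in 10.8% of 39145 windows of shared distal peaks. Of the paired windows 1 kb downstream 0.0715% had it, a ratio of 151. Paired windows that overlapped a peak were left out, so words that mostly lie in peaks are rarer in them by design. REST, a repressor of neuronal genes, had a ratio of 62.7, RFX 10.9 and NRF1 8.60. The REST word was rare, with 342 matches in all peaks of replicate 1 against 5602 for CTCF. Its ratio thus rests on few paired windows. SP and KLF factors had a ratio of 3.58, ZIC 2.63, the E-box CAGCTG 2.08 and the SOX word 1.28. In exact McNemar tests 25 of 44 words were higher in peaks, 9 were lower and 10 were not called.

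The homeodomain word TAATTA (0.525), the LHX word (0.685), the OTX word (0.618) and the GATA word (0.635) were lower in peaks. Peak windows had 52.9% GC and the paired windows 45.1%. Against the same windows shuffled with their dinucleotides kept, TAATTA turned to a ratio of 2.17, LHX to 1.93, the neuronal POU word to 1.94, FOXA to 1.72 and MEF2 to 2.43. Words for POU (2.02) and HOX with PBX (1.62), below 1 and not called against the flanks, were higher. NFI_HALF (0.674) and NFKB (0.714) turned lower. Of the 25 words higher against the flanks, 19 were also higher against the shuffled windows.

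**Figure D3:**
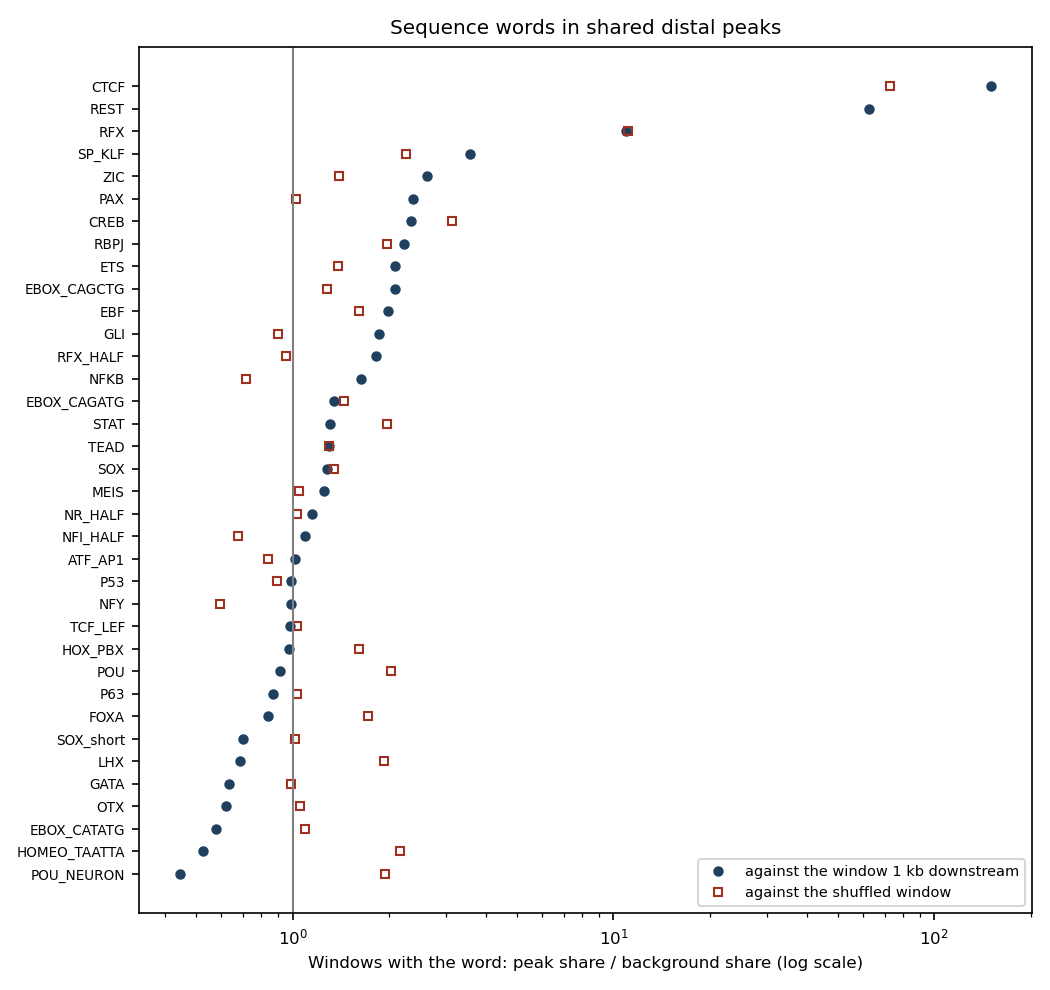
Ratio of windows with each word, for words found in at least 100 peak windows. Homeodomain, POU and FOXA words fall below 1 against the flank and above 1 against shuffled windows.

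CTCF words in peaks overlapped a deposited footprint, a short protected stretch, in 92.2% of cases in replicate 1 and 85.7% in replicate 2. An overlap of 1 bp was enough. Words moved to a random place within their peak gave 39.5% and 37.2%. REST words did so in 93.6% and 85.7%, and NRF1 words in 91.2% and 89.5%. The ZIC word did so in 27.9% and 26.5% against 19.8% and 19.0%. FOXA words (8.47% and 7.76%) were below their random values of 14.4% and 14.0%, as were GATA words (8.12% and 8.69% against 11.9% and 11.7%). TAATTA (10.9% and 8.94% against 12.6% and 11.5%) and POU words (13.4% and 12.4% against 17.6% and 15.3%) were below theirs too. The SOX_short, OTX, MEIS and NFI_HALF words also lay below all placements in both libraries. The SOX word lay above all in replicate 1 (16.4% against 15.5%) and below all in replicate 2 (13.1% against 14.5%). Placements were not matched on base content. In both libraries 15 of 44 words lay above all 100 random placements and 12 below all.

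There were 375904 footprints in replicate 1 and 328948 in replicate 2, with median widths of 9 and 8 bp. A footprint overlapped 66.9% and 69.9% of the peaks. The share rose with peak height, from 30.5% to 95.5% from the lowest to the highest quartile in replicate 1, and from 39.6% to 96.3% in replicate 2. Of the footprints, 31.7% in replicate 1 and 37.9% in replicate 2 overlapped a footprint of the other library. The footprints came from the other processing run than the peaks used here. Only 58.4% and 52.0% of them overlapped such a peak, against 84.6% and 84.9% with the longer list of scaled heights.

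**Figure D4:**
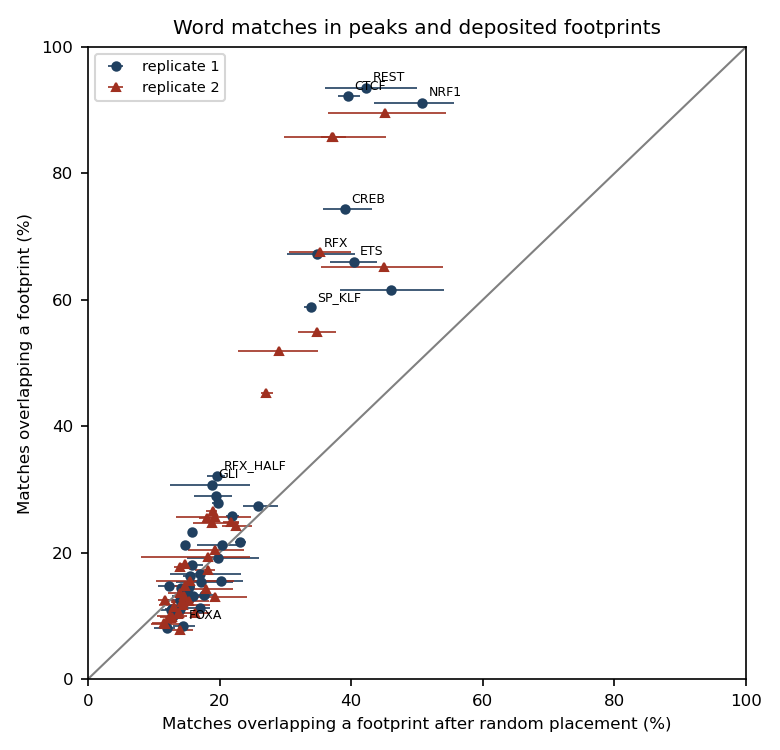
Share of word matches in peaks that overlap a footprint, against the share after random placement, for words with at least 100 matches. Bars span the lowest to the highest of 100 placements.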

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

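The tests of depth as the only difference, of peak height and depth at Hox promoters, of the processing run and of a more caudal tissue were chosen only after the results were seen. The Hox depth test was written when the Hox promoters without a peak in replicate 2 were known, and the caudal hypothesis arose from distal peak counts already seen. No result met a rule for outliers, for groups that differ or for signal in data not analysed. The 3 patterns below were chosen for weighing after their values were seen.

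More peaks were listed in replicate 1 (148508) than in replicate 2 (110912). A difference in depth alone would leave depth-scaled heights about equal. Their median ratio in shared peaks was 1.56, which argues against depth alone. The scaling totals were inferred from the other processing run, so this holds only if both runs counted the same tags. Peaks displaced within the same open region might account for part of the peaks of 1 library: 29.2% of them lay in a hotspot of the other library, between the bounds of 20 and 50% set before. Split by library after the result was seen, the share was 17.5% for replicate 1, under the lower bound, and 53.1% for replicate 2, over the upper. At promoters it was 69.4% and 83.5%, and at distal sites 10.5% and 40.1%. All 10 of the highest such peaks, including Vcl, Smarca4 and Kcnab2, lay in the other library's hotspot. Each of the 10 lay within 1 kb of a TSS, so they do not speak for distal peaks. Cells of another type in replicate 1 cannot be told apart: among the 8 lists of other tissues, the highest ratio of distal peaks relative to the pooled progenitor, dorsoventral, spinal and neurogenesis lists was 1.18 (germ cell genes), but the upper bound was under 1.5 for only 6 of the 8. Differences between the 2 dissections or in the yield of the nuclease cut stay open and were not tested.

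At 19 Hox genes, among them Hoxb3, Hoxb4, Hoxb5, Hoxc8, Hoxd9 and Hoxd10, replicate 1 had a promoter peak and replicate 2 had none. Random lists matched on the height in replicate 1 had a mean of 0.551 such genes and at most 4. The permutation p was 1e-04, the smallest possible with 10000 lists. These lists draw scattered genes, while many of the 19 lie side by side in stretches without a peak of replicate 2. The p thus counts linked promoters as separate genes, so the p alone cannot decide on height and depth. Replicate 1 heights at the 19 promoters ran from 229 to 1031. At shared promoter peaks the median unscaled ratio of replicate 1 over 2 was 2.00 (quartiles 1.57 and 2.75). In Hoxb, replicate 2 listed peaks down to a height of 61. Of all genes with a promoter peak in replicate 1, 3.11% had none in replicate 2. A genome-wide difference of that size would leave the 19 promoters above listed heights, so the values argue against it. The other processing run listed a peak of replicate 2 at 5.26% of these promoters, Hoxc10 alone, which argues against 1 run as the cause, although 25.2% of the stricter peaks of replicate 1 in the Hox clusters were absent from the longest list against 5.83% across the genome, and 10.2% against 6.09% in replicate 2. A more caudal tissue in replicate 1 may lower peaks near forebrain and midbrain genes relative to spinal genes: the difference in mean log2 height ratio was -0.027 (permutation p 0.631, bootstrap interval -0.127 to 0.0657), which leaves it open.

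Loss of calls in densely open stretches might also leave Hox promoters such as Hoxb5 without a peak of replicate 2. Outside the clusters 0 of 20 dense 50 kb windows, or 0%, had fewer than 0.25 times as many peaks in replicate 2, with an exact upper bound of 16.8%. The bound written before was under 2%, which the value of 0% meets. It was set aside after the result was seen, because 20 windows cannot show a share that low and because only 1 of 9 windows in the Hox clusters met the criterion itself. So calls lost in dense stretches and a difference in tissue cannot be told apart here. The heights above argue only against a genome-wide difference in height or depth.

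The highest shared distal peaks, near Pak3, Limd1, Cd209a and Kpna1, might come from sequence that is counted at several places. Copies of mitochondrial DNA are argued against: 0 of the 10 peaks matched the mitochondrial sequence over 100 bp at 90% identity. Another genomic match over 100 bp at 95% identity was found for 4 of the 10, those nearest Pak3 (97.1% identity), Limd1 (98.3%), Kpna1 (98.6%) and Dtnbp1 (95.9%), between the bounds of 1 and 5 set before, so repeated sequence stays open. No biological explanation was tested.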

How the results depend on the processing

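The list of scaled heights, hotspots, any TSS, a peak of each library in the window and all alternatives for the introns were chosen only after the data were seen; the other alternatives were planned. Where no cause is named below, the cause was not tested.

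The excess of distal peaks at neural over non-neural transcription factor genes kept its direction and its side of the threshold under all 7 alternatives. Differences ran from 5.19 (stricter list) to 14.1 (replicate 1 alone). None of the 7 matched the genes on CpG content or gene density. The lists above random in distal peaks numbered 14 or 15 in every alternative, against 15. Replicate 1 alone gave means of 29.75 (4.72 times random) for forebrain and midbrain factors, 28 (4.46) for spinal factors and 53.9 (8.55) for Hox genes. Replicate 2 alone gave 30.5 (6.67), 27.1 (5.94) and 34.3 (7.49). Over all lists, 158 of 168 alternative values for distal peaks kept direction and side of the threshold, 5 lost the call (housekeeping in 4, and synapse and glia in the stricter list), 1 gained it (erythroid, CpG-matched) and 4 turned. The turned lists were uncalled: within 20 kb erythroid (0.921 times random), immune (0.865) and germ cell genes (0.874), and immune genes between 0.995 and 1.44 with 1 library left out.

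For promoters 155 of 189 values kept both, 20 lost the call, 1 gained it and 13 turned. The lists above numbered 6, against 9, with a 500 bp window (neural progenitor, neural crest and somite lost the call) and with the stricter list (neural crest, patterning and somite). Matching on CpG content left 3 lists above and 3 below, against 9 and 6. The spinal and forebrain lists, fully open, could not pass it. The neural progenitor, dorsoventral, patterning, neural crest and housekeeping lists also lost the call. Under this matching erythroid (25%), endothelial (46.7%), epidermis (53.3%) and non-neural factors (51.9%) turned from below to above their random means without a call. Heart and muscle, next to the mean of all genes, turned with a 500 bp window (46.7%), the stricter list (33.3%), the scaled list (60.0%), each library in the window (60.0%) and either library alone (60.0%). Synapse and glia genes turned with the stricter list (58.8%) and non-neural factors with any TSS (63.5%). Hox genes ranged from 35.9% to 84.6% with 1 library left out and turned, with a call, in replicate 1 alone. The count of open Hox promoters then ranged from 14 to 33, against 12.

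The overlap of replicate 1 with replicate 2, 48.4%, became 37.1% with a reciprocal overlap, 58.8% with the stricter list, 60.4% with equal numbers, 55.6% with the scaled list and 52.0% with hotspots. The Spearman coefficient, 0.286, became 0.909 in shared peaks, 0.660 in the stricter list and 0.573 in the scaled list. The Pearson coefficient, -0.11, turned positive in shared peaks (0.91), the stricter list (0.18), the scaled list (0.12) and with a pseudocount of 10 (0.11), and was -0.22 with 0.1. Absent peaks enter it as the pseudocount. The promoter share of shared peaks, 29.8%, was 41.3% in the stricter list, 30.9% with equal numbers, 22.3% with 500 bp, 38.3% with 2.5 kb and 20.4% to 29.4% with 1 library left out. The total of 88 peaks at the introns, Sox2 and Olig2 was 53 in the stricter list and 130 to 138 with 1 library left out. Footprints overlapping the other library, 31.7% and 37.9%, were 20.8% and 23.8% by reciprocal overlap and 43.2% and 49.97% inside shared peaks.

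For words 210 of 263 values kept both, 13 lost the call, 13 gained it and 27 turned. Shuffled windows, which match the base content of the peaks, left 5 words lower against 9, and gave no ratio for REST, whose word was in none of them. Turned upward were SOX_short (1.02), CATATG (1.097), TAATTA (2.17), HOX with PBX (1.62), OTX (1.06), POU (2.02), neuronal POU (1.94), TCF and LEF (1.03), FOXA (1.72), MEF2 (2.43), P63 (1.03) and LHX (1.93). Turned downward were RFX_HALF (0.956), NFI (0.741), NFI_HALF (0.674), GLI (0.9), ATF_AP1 (0.840) and NFKB (0.714). ATF_AP1, near 1, also turned with upstream windows (0.992), 100 bp windows (0.967) and the stricter list (0.869). NFY turned with the stricter list (1.02) and P53 with upstream windows (1.04). With 1 library left out, HOX with PBX ranged from 0.913 to 1.13, TCF and LEF from 0.997 to 1.06, NFY from 0.934 to 1.02 and P53 from 0.990 to 1.00.

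What depth limits was not tested, since no reads were used. The scaling totals were 247.9 and 210.5 M, a ratio of 1.18.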

Other observations

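The test of CpG content was written before its result was seen, and the other values in this part were looked at only after the data were seen. Non-neural developmental transcription factor genes with open promoters, such as Hand2 and Pdx1, may reflect promoter CpG content: 27 of the 52 were open, against a mean of 25.2 in random lists matched on it, with 95% of those lists between 20 and 31. A count inside that range was written before as agreement. This was set aside after the result was seen, because without matching the list did not differ from the other genes either (51.9%, adjusted p 0.324). So the test cannot tell whether CpG content plays a part.

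Runs of low peaks were found in 1 library only. On chromosome 11, from 112100001 to 112200000, replicate 1 had 90 peaks with a median height of 23.5 and replicate 2 had 3. On chromosome 16, from 6100001 to 6200000, replicate 1 had 0 and replicate 2 had 60 with a median height of 15.

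Over all genes, distal peaks were 1.38 times as many in replicate 1 as in replicate 2. The ratio was 1.57 near Hox genes, where neighbours count the same peaks, 0.975 near forebrain and midbrain factors and 1.82 near receptor genes. It was 1.09 near the pooled genes of the progenitor, dorsoventral, spinal and neurogenesis lists.

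CpG-rich windows made up 7.93% of all shared distal peaks and 13.2% of those near the 20 genes with the most distal peaks. Across the gene lists, receptor genes not counted, the share ranged from 2.13% (germ cell genes) to 25.3% (notochord and floor plate genes). It was 17.1% near neural progenitor genes, 22.4% near dorsoventral progenitor factors, 19.6% near erythroid genes and 7.79% near liver and gut genes. A window of 500 bp was called CpG-rich with a GC content over 50% and an observed to expected CpG ratio over 0.6.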
